A study of Rattus norvegicus with 14 samples.

How the data were processed

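The series holds RNA-seq of cultured rat aortic smooth muscle cells in 14 libraries, made with a stranded kit from polyadenylated RNA and read as 40 base single ends, per the labels' protocols. ERCC spike-in transcripts were added in proportion to the RNA of a fixed number of cells, per the labels, which leaves open whether cell number or RNA amount set the dose. The authors deposited 2 tables of 17404 features each (17312 genes and 92 spike-ins). One holds unnormalised FPKM and the other normalised FPKM, both deposited by the authors with 1 column per library. Reads were processed with HISAT and Cufflinks 2.0.0 on genome build rn6, per the submitters' processing notes, and the annotation is not given in the sources used here. The method of normalisation is not stated. From the values, the normalised FPKM equal the unnormalised FPKM plus about 0.1, adjusted by a smooth curve in each library that brings spike-ins together: over spike-ins at 1 FPKM or more in every library, the library medians ranged from -0.42 to 0.37 (log2) before and from -0.12 to 0.11 after. An FPKM of 0 became 0.088 to 0.111. The curve moved low and high values unequally in most libraries. Low values moved up most in PDGF 2 h replicate 1 (1.08 against -0.02 for high values, log2) and PDGF 24 h replicate 0 (0.98 against 0.42), and the counts of genes, overlaps and list members on the spike-in scale were repeated without these 2 libraries, an alternative chosen after seeing the data. The gap between low and high values was wider than in the latter in PDGF 24 h replicate 2 (-0.28 against 0.44) and JQ1 plus PDGF 2 h replicate 1 (0.30 against -0.29), and low values moved down in JQ1 plus PDGF 2 h replicate 0 (-0.65 against -0.37) and JQ1 plus PDGF 24 h replicate 1 (-0.57 against -0.23). These were left out only 1 at a time.

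Columns were put in groups by their names, which match the group of the sample titles. They end in digits, whereas the titles carry letters, so no column was tied to 1 sample and libraries are named by group and column digit. The tables had 0 columns without a group. Groups, tests, gene lists and the rule for named genes were fixed before the data were examined.

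Genes with a normalised FPKM of at least 1 in at least 2 libraries were tested (10133 genes). The test was limma 3.58.1 in R 4.3.3 on log2(normalised FPKM + 1), with 1 linear model over all 5 groups, 9 residual degrees of freedom, contrasts and empirical Bayes moderation with a mean trend. Calls had a Benjamini-Hochberg adjusted p under 0.05. FPKM are not counts, so no count model was used. Depth is unknown: low values fell on whole-number ratios, but which step was 1 read was ambiguous in several libraries, and the number of genes above 0 (9901 to 11503) stands in for it. With no depth, a low value carries no interval, and exact zeros may be failed estimates. The median-centred scale divides unnormalised FPKM by size factors (9981 genes tested). No coordinates are printed because the rn6 genome was not used here.

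The 16 gene lists hold 318 genes, of which 12 were not analysed here because no feature carried the symbol (Chaf1a, Cenpe, Clec3b, Lama2, Col4a2, Relb, Tnfaip3, Rrp12, Mkl1, Mkl2, Mef2c and Tead4). The 15 lists with at least 3 tested genes were tested in 5 comparisons (75 tests, adjusted together) with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of the 38 list calls, 8 also passed with an estimated correlation. The leukocyte list had 2 tested genes and was not tested. Named genes were, for each of the first 5 comparisons, the 10 highest and 10 lowest log2 differences among genes that passed, whose group ranges did not overlap and that had a gene symbol; up to 4 members of each list with the largest differences past the threshold; and 15 genes fixed in advance. For the interaction they were the 5 highest and 5 lowest without the condition on ranges. Not all of these are printed: examples were drawn from them after their values were seen, by preference where the call held under the alternatives. In each of the first 5 comparisons 2 or 3 of the 20 top genes were microRNA loci, which are short. The multi-copy or short genes Rn28s, Rpl37 and Rpl37a are also uncertain.

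Simulated data with the real means and spread, and 200 changed genes per comparison, were used to test the code. The changed genes were drawn only from those with a mean log2(normalised FPKM + 1) above 2. Recovery of genes with lower values was not tested. Of genes changed 4-fold, 96.05% were recovered for PDGF at 2 h against 0 h, 100% for PDGF at 24 h against 0 h, 100% for PDGF at 24 h against 2 h, 98.36% for JQ1 at 2 h and 98.46% for JQ1 at 24 h, among 10133 genes each. Of genes changed 1.5-fold, 42.86, 27.27, 42.65, 34.85 and 34.85% were recovered in the same order, with 8, 5, 12, 7 and 6 false calls. In a simulated list shift camera called the shifted list and 0 of 74 other tests. The simulated genes varied independently, whereas the estimated correlation of the real lists ran from 0.0862 (G2/M) to 0.697 (matrix). The simulation therefore does not show how often camera calls falsely in lists whose genes move together. These correlations were estimated on the spike-in scale only, where shifts that a library shares across genes can enter them. A list of interferon-response genes described below had an estimated correlation of 0.25 on that scale and 0.00803 on the median-centred scale. A call lost with an estimated correlation may therefore reflect the scale. Alternatives tried were both unnormalised scalings, spike-in medians, a pseudocount of 0.1, no filter and a filter of 5 FPKM, fits of the compared groups alone, robust variance, a log2 difference of at least 1, and leaving out each library. Figures were drawn with matplotlib 3.10.9.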

Results

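Polyadenylated RNA was sequenced from rat aortic smooth muscle cells, the contractile cells of the vessel wall, obtained from a commercial supplier and grown in culture. The cells were kept without serum for 24 h and then given platelet-derived growth factor (PDGF), a mitogen under which smooth muscle cells are known to lose contractile gene expression, at 925 ng/ml per the labels. Some cells were first treated for 3 h with JQ1 at 500 nM, a small molecule that displaces the BET bromodomain proteins from acetylated histones. The 14 libraries fell into 5 groups, with 2 unstimulated libraries (0 h) and 3 each of PDGF at 2 h, JQ1 plus PDGF at 2 h, PDGF at 24 h and JQ1 plus PDGF at 24 h. The comparisons ask how PDGF changed transcript levels early and late, and how those levels differed when BET proteins were inhibited. Unstimulated libraries at 2 and 24 h and libraries with JQ1 alone were not analysed here. PDGF and time in culture therefore enter the comparisons with 0 h together. The comparison of PDGF at 24 h with 2 h likewise cannot separate longer PDGF from longer culture. Nothing in the labels says that replicates came from separate cultures. The p-values then measure only the spread between these samples, which may be technical. Sample titles carry letters from A to D without JQ1 and from E to H with JQ1. Whatever the letters stand for cannot be told apart from JQ1 in any JQ1 comparison.

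Between 9901 and 11503 of the 17312 genes were above 0 in a library. The values are FPKM (fragments scaled by transcript length and library size), so the number of reads per library is unknown. Levels are normalised FPKM with the SD, n = 2 for the unstimulated group and n = 3 for the others. Differences are log2 of the value plus 1, with the SE of the limma fit and a Benjamini-Hochberg adjusted p. This scale understates the change of genes with low values. Spearman correlations between replicates, taken across genes, which are not independent replicates, lay between 0.945 (a pair of PDGF 2 h libraries) and 0.989 (a pair of PDGF 24 h libraries).

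Synthetic spike-in transcripts made up 2.66 ± 0.18% (SD, n = 2) of the unnormalised FPKM in unstimulated cells. Their share was 2.08 ± 0.24% (SD, n = 3) with PDGF at 2 h and 1.80 ± 0.13% (SD, n = 3) with PDGF at 24 h, against 2.38 ± 0.084% and 2.45 ± 0.22% (SD, n = 3 each) with JQ1 plus PDGF at the same times. On the authors' spike-in scale the median log2 difference of the tested genes was 0.01 for PDGF at 2 h against 0 h, 0.41 for PDGF at 24 h against 0 h, 0.40 for PDGF at 24 h against 2 h, -0.29 for JQ1 at 2 h and -0.48 for JQ1 at 24 h. Counts of genes are given on this scale and on a median-centred scale, where unnormalised values are divided by size factors and such a shift is absent. The size factors lay between 1.016 and 1.024, so the unnormalised values were already close to median-centred.

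**Figure D1:**
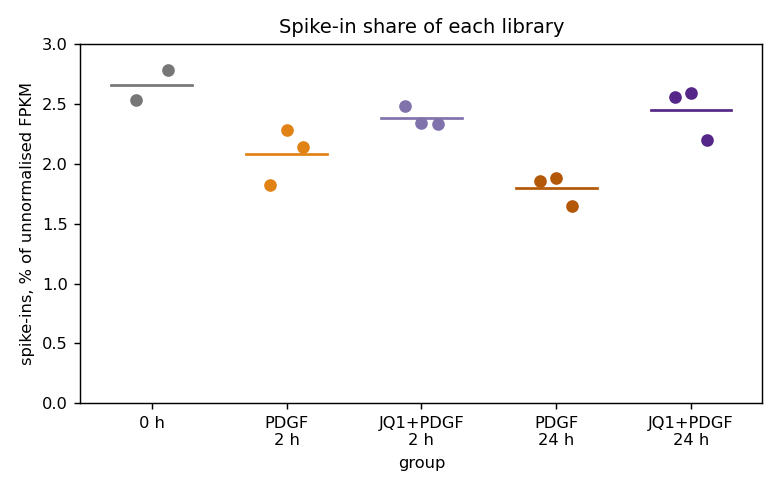
Spike-in transcripts as a percent of unnormalised FPKM in each of the 14 libraries (points) with the group mean (line). The 3 PDGF 24 h libraries lie between 1.65 and 1.88%, and the 3 libraries with JQ1 plus PDGF at 24 h lie between 2.20 and 2.59%.

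After 2 h of PDGF, immediate early genes and most inflammatory genes were above unstimulated levels. All 26 immediate early genes, which a mitogen induces without new protein synthesis, rose (26 adjusted over the list alone). Dusp5, an ERK phosphatase, rose by 6.04 ± 0.24 and the nuclear receptor gene Nr4a3 by 6.02 ± 0.21, while Fosl1 and Fosb, which encode AP-1 subunits, rose by 5.66 ± 0.25 and 5.39 ± 0.22. The transcription factor gene Egr1 went from 14.7 ± 0.18 (SD, n = 2) to 390 ± 66.7 normalised FPKM (SD, n = 3). Of 16 inflammatory genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone). Ccl7, a monocyte chemokine, rose most of all genes that met the naming rule, from 3.16 ± 0.81 (SD, n = 2) to 424 ± 27.5 normalised FPKM (SD, n = 3), a log2 difference of 6.69 ± 0.20 (limma, adjusted p = 4.33e-12). The related chemokine gene Ccl2 rose by 6.01 ± 0.20, the cytokine gene Lif by 5.79 ± 0.33 and Ptgs2, which encodes the inducible cyclooxygenase, by 5.08 ± 0.23.

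Of 20 amino acid and ER stress response genes, 18 rose (18 adjusted over the list alone), among them Chac1, which encodes a glutathione-degrading enzyme, by 3.19 ± 0.16 and the amino acid transporter gene Slc7a5 by 1.95 ± 0.15. Of 21 ribosome biogenesis genes, 15 rose and 6 did not pass (17 rose adjusted over the list alone). Rrp9 and Nop58, whose products act in pre-ribosomal RNA processing, rose by 1.38 ± 0.16 and 1.22 ± 0.15. Of 17 glycolysis genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone), led by Hk2, which encodes a hexokinase, at 3.81 ± 0.17 and the glucose transporter gene Slc2a1 at 1.46 ± 0.16. In cholesterol synthesis 7 of 20 genes rose and 3 fell, the same numbers adjusted over the list alone, with Msmo1 higher by 1.52 ± 0.12.

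Matrix and state genes moved in part. In the matrix protease list 6 of 13 genes rose and 2 fell (6 and 2 adjusted over the list alone). Plaur, the urokinase receptor gene, rose by 5.45 ± 0.15 and Plat, which encodes tissue plasminogen activator, by 3.38 ± 0.13. Of 20 extracellular matrix genes, 6 rose and 14 did not pass (6 rose adjusted over the list alone), with the matricellular genes Tnc and Thbs1 higher by 4.31 ± 0.18 and 3.46 ± 0.21. Among 30 transcription factors of smooth muscle state, 15 rose and 3 fell (16 and 3 adjusted over the list alone). Ets2 rose by 3.88 ± 0.19, Sox9 by 3.42 ± 0.16 and Klf4, a known repressor of contractile genes, by 1.85 ± 0.17. Of 23 contractile genes, 5 rose and 18 did not pass (4 rose adjusted over the list alone), and on the median-centred scale 5 rose and 3 fell. Cnn1, the calponin gene, rose by 1.07 ± 0.19, whereas Acta2, the smooth muscle actin gene, stood at 5251 ± 618 (SD, n = 2) before and 6012 ± 927 (SD, n = 3) after PDGF (adjusted p = 0.467).

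Many mitosis genes, but few genes of DNA replication, were lower at 2 h. Of 22 G2/M and mitosis genes, 13 fell and 9 did not pass (13 fell adjusted over the list alone), with the kinase genes Plk1 and Aurka lower at -1.28 ± 0.21 and -1.05 ± 0.22. In the G1/S and DNA replication list 4 of 25 fell (2 adjusted over the list alone, 7 lower and 1 higher when centred), of which Tyms, the thymidylate synthase gene, moved most (-1.08 ± 0.19). Of 7 BET and P-TEFb genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone, 1 and 3 on the median-centred scale), with Brd3 at -1.01 ± 0.19 and Hexim1, which encodes the inhibitor of the P-TEFb kinase, at -0.74 ± 0.15. Beyond the lists and leaving microRNA loci aside, the genes that fell most included Txnip (-4.03 ± 0.18), an inhibitor of thioredoxin, the transcription factor gene Klf15 (-3.41 ± 0.26), the inhibitory Smad gene Smad6 (-3.04 ± 0.28) and the Notch ligand gene Jag1 (-2.65 ± 0.15). The metallothionein gene Mt1a rose by 6.13 ± 0.40, the follistatin gene Fst by 5.86 ± 0.28 and Rgs16, a regulator of G protein signalling, by 5.62 ± 0.27. Markers of other cell types moved little: 0 of 5 endothelial markers and 0 of 2 leukocyte markers passed in limma (1 and 0 at an unadjusted p under 0.05), and 1 of 6 adventitial fibroblast markers fell.

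In limma 3078 of 10133 genes passed at 2 h, 1796 higher and 1282 lower (2032 and 1936 on the median-centred scale). The immediate early list (mean 3.25 above all other genes, adjusted p = 4.11e-32) and the inflammatory list (2.69, adjusted p = 1.91e-10) passed in camera, and each also with an estimated correlation (adjusted p = 0.0317 for both). The lists of amino acid and ER stress response (adjusted p = 5.99e-10), ribosome biogenesis (4.19e-07), G2/M (6.8e-05, lower), matrix proteases (0.000105), state transcription factors (0.000105), glycolysis (0.00158) and matrix (0.00442) passed with the preset correlation. They did not with an estimated correlation, where the adjusted p was 0.19, 0.312, 0.129, 0.261, 0.456, 0.481 and 0.72 in that order. Contractile (adjusted p = 0.476), G1/S (0.0668), cholesterol (0.195), BET (0.536), endothelial (0.802) and fibroblast (0.22) lists did not pass. The BET list had a median of 0.01 and a mean of -0.13. The number of genes rested on the unstimulated pair, since fewer passed in both directions when either library of the pair was left out. The remaining lone library was then assumed to vary like the other groups. When only these 5 libraries were fitted, which keeps the pair, 1537 genes passed (1063 higher and 474 lower). The same setting gave 5027 genes for PDGF at 24 h against 0 h, and the cause of the drop at 2 h was not tested.

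**Figure D2:**
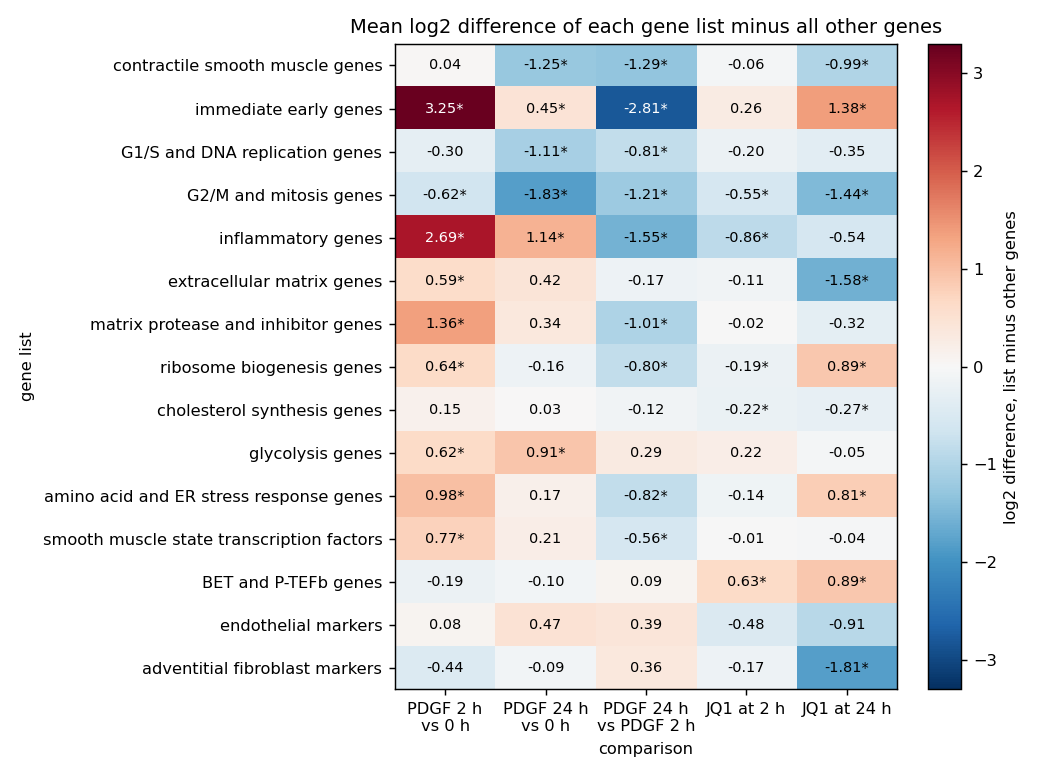
Mean log2 difference of each of 15 gene lists minus that of all other tested genes (colour and number) in the 5 comparisons, with an asterisk where the camera adjusted p was under 0.05. Immediate early genes stand at 3.25 after 2 h of PDGF, and matrix genes at -1.58 with JQ1 at 24 h.

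After 24 h of PDGF, most contractile and cell cycle genes of the lists were below unstimulated levels, while most inflammatory and glycolysis genes were above them. Of 23 contractile genes, 14 fell and 2 rose (14 and 3 adjusted over the list alone, 17 and 2 on the median-centred scale). Acta2 went from 5251 ± 618 (SD, n = 2) to 945 ± 87 normalised FPKM (SD, n = 3), a difference of -2.47 ± 0.18 (limma, adjusted p = 8.34e-08). Cnn1 fell by 2.79, Myl9, a myosin light chain gene, by 2.44, and Tagln, which encodes the actin-binding protein transgelin, by 2.33. Itga7, an integrin gene, went the other way and rose by 2.91 ± 0.16. Myocd, the coactivator of contractile genes, fell by 1.32, and Myh11, the smooth muscle myosin heavy chain gene, by 1.14. Of 22 G2/M genes, 21 fell (21 adjusted over the list alone), with Top2a at -1.97 ± 0.21 and Ccna2, the cyclin A gene, at -1.87 ± 0.22. In the G1/S list 15 of 25 fell (18 adjusted over the list alone), among them Rrm2, a ribonucleotide reductase subunit gene, at -1.72 ± 0.27. Ccnd1, the cyclin D1 gene, which stood at 84.9 ± 11.9 (SD, n = 3) after 2 h, rose from 87.3 ± 5.3 (SD, n = 2) to 336 ± 35.7 normalised FPKM (SD, n = 3) by 24 h.

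Of 16 inflammatory genes, 12 rose and 1 fell at 24 h (13 and 1 adjusted over the list alone). Ccl7 was still higher by 6.09 ± 0.20 and Ccl2 by 5.10 ± 0.20, while the chemokine gene Cxcl12 fell by 2.26. Of 17 glycolysis genes, 16 rose (16 adjusted over the list alone, 15 on the median-centred scale), with the lactate transporter gene Slc16a3 higher by 2.72 ± 0.26 and Ldha, a lactate dehydrogenase gene, by 1.47 ± 0.12. In the matrix list 10 of 20 genes rose and 4 fell (12 and 4 adjusted over the list alone, 7 and 6 on the median-centred scale). Mgp, which encodes an inhibitor of calcification, rose from 658 ± 24.8 (SD, n = 2) to 14990 ± 1130 normalised FPKM (SD, n = 3), and Spp1, the osteopontin gene, from 6187 ± 940 (SD, n = 2) to 41310 ± 2450 (SD, n = 3). Of 26 immediate early genes, 16 were still higher and 3 were lower (16 and 3 adjusted over the list alone, 13 and 6 on the median-centred scale), with Fosl1 at 2.70 ± 0.25 and Jun at 2.31 ± 0.14. Outside the lists, Ptprn (5.90 ± 0.21), the pyrophosphate transporter gene Ankh (5.26 ± 0.18) and the connexin gene Gja4 (5.07 ± 0.17) were among the genes that rose most. The natriuretic peptide clearance receptor gene Npr3 (-4.91 ± 0.17) and the growth factor gene Fgf18 (-4.64 ± 0.57) fell most. Rpl37, a ribosomal protein gene that every cell uses, and the microRNA loci Mir31 and Mir3561 were listed at 0 in both unstimulated libraries, so no fold is given. Their unnormalised FPKM in the PDGF 24 h libraries were 457, 435 and 560 for Rpl37, 25, 81 and 297 for Mir31, and 44.9, 24.2 and 200 for Mir3561, and Rpl37 was also listed at 0 in PDGF 2 h replicate 1 and JQ1 plus PDGF 2 h replicate 0.

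The other lists depended on the scale at 24 h. In the state transcription factor list 19 of 30 genes rose and 2 fell (20 and 2 adjusted over the list alone), against 10 and 4 on the median-centred scale, with the homeobox gene Prrx1 higher by 2.64 ± 0.19. Of 13 matrix protease genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone), against 5 and 3 centred. The corresponding counts were 11 and 1 of 20 amino acid and ER stress genes (11 and 1 adjusted over the list alone, 6 and 4 centred). For cholesterol synthesis 10 of 20 rose (10 adjusted over the list alone), but 2 rose and 5 fell when centred. For ribosome biogenesis 6 of 21 rose (2 adjusted over the list alone, and 2 without PDGF 2 h replicate 1 and PDGF 24 h replicate 0), whereas 6 fell when centred, and for BET genes 4 of 7 rose (4 adjusted over the list alone), whereas 1 fell when centred. Markers of other cell types moved with PDGF at 24 h: 3 of 5 endothelial markers rose (4 adjusted over the list alone, 2 centred), with Eng at 1.49 ± 0.17, Cd14 of the leukocyte markers rose by 1.90 ± 0.24, and 2 of 6 fibroblast markers rose (2 adjusted over the list alone), against 1 higher and 2 lower when centred.

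In limma 4314 genes passed for PDGF at 24 h against 0 h, 3823 higher and 491 lower (1483 and 1338 on the median-centred scale). The G2/M list (mean 1.83 below all other genes, adjusted p = 4.11e-32) and the G1/S list (1.11 below, adjusted p = 2.7e-16) passed in camera and also with an estimated correlation (adjusted p = 0.00171 and 0.028). The contractile (adjusted p = 4.61e-16), glycolysis (1.71e-07), inflammatory (0.00403) and immediate early (0.0191) lists passed with the preset correlation, and their adjusted p was 0.0868, 0.238, 0.251 and 0.72 with an estimated correlation. Matrix (adjusted p = 0.312), protease (0.195), ribosome (0.752), cholesterol (0.341), amino acid (0.106), transcription factor (0.21), BET (0.883), endothelial (0.392) and fibroblast (0.753) lists did not pass, although on the median-centred scale the ribosome list did, as lower (adjusted p = 0.011). Camera compares t-statistics and not mean differences. The ribosome and fibroblast lists had means of 0.25 and 0.32 but stood below other genes in camera. The BET list stood above other genes in camera, with a mean 0.10 below theirs. Without unstimulated replicate 0 the count was 2489 (2126 higher and 363 lower).

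Between 2 and 24 h of PDGF most immediate early and inflammatory genes fell. Of 26 immediate early genes, 25 fell and 1 rose (25 and 1 adjusted over the list alone). Nr4a3 went from 163 ± 19.3 to 3.16 ± 0.96 normalised FPKM (SD, n = 3 each), a difference of -5.32 ± 0.19 (limma, adjusted p = 2.61e-11), and Nr4a1, Fosb and Egr3 fell by 5.16, 5.03 and 4.90. In the inflammatory list 11 of 16 fell and 1 rose (12 and 1 adjusted over the list alone), with Lif lower by -3.67 ± 0.29 and Ptgs2 by -2.93 ± 0.20. Of 23 contractile genes, 14 fell and 3 rose (14 and 3 adjusted over the list alone). Cnn1 fell by 3.87, Acta2 by 2.66 and Tagln by 2.57. Of 22 G2/M genes, 14 fell (15 adjusted over the list alone, 21 centred), with Ccna2 at -1.81 ± 0.20, and of 25 G1/S genes, 14 fell and 1 rose (14 and 1 adjusted over the list alone), with Mcm5, a subunit gene of the replicative helicase, at -1.12 ± 0.17. In ribosome biogenesis 12 of 21 fell and 1 rose (13 and 1 adjusted over the list alone, 19 lower when centred), for example Nop58 at -1.11 ± 0.13. For amino acid and ER stress genes the counts were 11 lower and 3 higher of 20 (12 and 3 adjusted over the list alone), where Chac1 fell by 2.34 and Ddit4, an inhibitor of mTORC1 signalling, rose by 2.75 ± 0.15.

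Matrix and metabolic lists were mixed between 2 and 24 h. Mgp rose by 3.56 ± 0.13 and Vcan, the versican gene, by 2.19 ± 0.15, whereas Thbs1 fell by 2.74 and Tnc by 2.39, and in all 8 of 20 matrix genes rose and 6 fell (9 and 7 adjusted over the list alone, 7 and 10 centred). Of 13 protease genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone, 1 and 7 centred), with Plaur at -3.95 ± 0.13. Of 17 glycolysis genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone), where Hk2 fell by 2.79 and the phosphofructokinase gene Pfkm rose by 1.58 ± 0.14. Cholesterol genes gave 10 higher and 5 lower of 20 (11 and 5 adjusted over the list alone, 5 and 7 centred). Of 30 state transcription factors, 10 rose and 15 fell (10 and 15 adjusted over the list alone, 5 and 17 centred), where Prrx1 rose by 2.55 ± 0.17 and Sox9 fell by 2.27. Of 7 BET and P-TEFb genes, 4 rose (4 adjusted over the list alone), against 2 higher and 2 lower when centred, with Hexim1 at 1.35 ± 0.13. Txnip, which fell by 4.03 at 2 h, rose by 4.97 ± 0.16 between the times. Of the markers, 3 of 5 endothelial, 3 of 6 fibroblast and 1 of 2 leukocyte genes rose and 1 leukocyte gene fell (the same numbers adjusted over the list alone), with Pdgfra, a fibroblast marker here, at 2.19 ± 0.20 and Cd14 at 1.52 ± 0.21.

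In limma 5703 genes passed between PDGF at 2 and 24 h, 4510 higher and 1193 lower at 24 h (2664 and 2576 on the median-centred scale). Immediate early (mean 2.81 below all other genes, adjusted p = 1.53e-31), G2/M (9.18e-12) and inflammatory (1.76e-08) lists passed in camera and also with an estimated correlation (adjusted p = 0.0317, 0.028 and 0.0334). The contractile (adjusted p = 1.19e-10), ribosome (3.41e-08), G1/S (1e-06), amino acid (1.02e-06), transcription factor (0.000259) and protease (0.00211) lists, all with means below those of other genes, passed with the preset correlation, and their adjusted p was 0.185, 0.264, 0.0978, 0.309, 0.481 and 0.34 with an estimated correlation. Matrix (adjusted p = 0.441), cholesterol (0.577), glycolysis (0.0991), BET (0.56), endothelial (0.493) and fibroblast (0.515) lists did not pass, although on the median-centred scale the glycolysis list did, as higher (adjusted p = 0.0403). The matrix and cholesterol lists had means of 0.17 and 0.22 but stood below other genes in camera.

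With JQ1 before PDGF, many inflammatory and mitosis genes were lower at 2 h than with PDGF alone, while Hexim1 was higher and immediate early genes went both ways. Ccl7 went from 424 ± 27.5 to 66 ± 16.2 normalised FPKM (SD, n = 3 each), a difference of -2.69 ± 0.18 (limma, adjusted p = 4.74e-08). Ccl2 fell by 2.68 and Il6, the interleukin gene, by 2.57, and in all 11 of 16 inflammatory genes fell and 1 rose (11 and 1 adjusted over the list alone, 10 and 4 on the median-centred scale). Hexim1, whose transcript is a known readout of BET inhibition, rose from 22.7 ± 4.46 to 98.5 ± 5.26 (SD, n = 3 each), a difference of 2.08 ± 0.13. In its list of 7 BET and P-TEFb genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone). Of 22 G2/M genes, 16 fell (16 adjusted over the list alone, 12 centred), with Ube2c at -1.79 ± 0.30 and Cdc20 at -1.63 ± 0.21, both of which act at the anaphase-promoting complex. Of 25 G1/S genes, 13 fell and 2 rose (13 and 2 adjusted over the list alone, 11 and 2 centred), for example the helicase subunit gene Mcm3 at -1.56 ± 0.19.

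Ribosome biogenesis genes fell for 13 of 21 (13 adjusted over the list alone), against 9 lower and 2 higher when centred, with Nop2 at -1.31 ± 0.16. Of 20 cholesterol genes, 13 fell and 2 rose (14 and 2 adjusted over the list alone, 9 and 2 centred), with Fdft1, the squalene synthase gene, at -1.39 ± 0.16. Of 20 amino acid and ER stress genes, 10 fell and 3 rose (10 and 3 adjusted over the list alone, 8 and 5 centred), where Trib3, a pseudokinase gene, fell by 2.23 and Phgdh, which encodes an enzyme of serine synthesis, by 1.66. The immediate early list changed sign with the scale, with 6 of 26 higher and 9 lower (7 and 10 adjusted over the list alone) against 13 higher and 5 lower when centred. Fos rose by 1.51 ± 0.22 and Nr4a3 fell by 1.33. Of 20 matrix genes, 7 fell (7 adjusted over the list alone), against 7 higher and 5 lower when centred, with Tnc at -2.21 ± 0.17. Of 13 proteases and inhibitors, 6 fell and 3 rose (7 and 3 adjusted over the list alone), with the inhibitor gene Timp1 higher by 1.15 ± 0.12. Of 17 glycolysis genes, 5 fell and 2 rose (5 and 2 adjusted over the list alone), against 1 and 6 centred, with Hk2 at -0.98 ± 0.15.

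Contractile genes were split with JQ1 at 2 h after PDGF. Of 23, 9 fell and 3 rose (9 and 3 adjusted over the list alone), against 6 lower and 8 higher when centred and 6 lower and 1 higher without PDGF 2 h replicate 1 and PDGF 24 h replicate 0. Pln, the phospholamban gene, fell by 2.40, and Lmod1, which encodes leiomodin, by 0.92. Acta2 stood at 6012 ± 927 with PDGF and 6198 ± 189 with JQ1 plus PDGF (SD, n = 3 each; adjusted p = 0.814), although it rose by 0.43 on the median-centred scale. Of 30 state transcription factors, 11 fell and 3 rose (11 and 3 adjusted over the list alone), against 8 and 7 centred. Klf2 rose by 2.90 ± 0.17 and Klf4 by 0.76 ± 0.15, whereas Prrx1 fell by 2.61, Myocd by 1.73 and Sox9 by 1.20. Ccnd1 fell by 0.99 and Pdgfrb, a PDGF receptor gene, by 0.79. Outside the lists, Rgs16 (-4.03 ± 0.24), the potassium channel gene Kcnn4 (-3.62 ± 0.20), the interferon-inducible genes Igtp (-3.45 ± 0.25), Oas1b (-3.40 ± 0.30) and Oasl2 (-3.38 ± 0.23), the chloride channel gene Ano1 (-3.37 ± 0.16) and Fst (-3.27 ± 0.25) were among the genes that fell most. Polg2, a mitochondrial DNA polymerase subunit gene, rose by 3.41 ± 0.24 and the kinase gene Mknk2 by 2.51 ± 0.15. The locus Mir212 was listed at 0 in all PDGF 2 h libraries and at 51.8, 333 and 31 unnormalised FPKM with JQ1. Markers of other cell types were also lower: 2 of 5 endothelial (Erg -1.91 ± 0.37, Eng -1.44 ± 0.15), Cd14 (-1.93 ± 0.21) and 3 of 6 fibroblast markers fell (2, 1 and 4 adjusted over the list alone, and 2, 1 and 1 centred), with Pdgfra at -1.63 ± 0.20.

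In limma 4183 genes passed for JQ1 at 2 h, 734 higher and 3449 lower (2003 and 2146 on the median-centred scale). In camera the G2/M (mean 0.55 below all other genes, adjusted p = 0.000959), inflammatory (0.86 below, 0.0252), ribosome (0.0229, lower), cholesterol (0.0252, lower) and BET (0.63 above, 0.0411) lists passed. None did with an estimated correlation, where the adjusted p was 0.19, 0.34, 0.72, 0.694 and 0.316. On the median-centred scale the ribosome (adjusted p = 0.153) and cholesterol (0.0599) lists did not pass and the immediate early list did (0.0421). Contractile (adjusted p = 0.874), immediate early (0.0894), G1/S (0.242), matrix (0.297), protease (0.909), glycolysis (0.341), amino acid (0.422), transcription factor (0.799), endothelial (0.441) and fibroblast (0.522) lists did not pass. The immediate early, glycolysis and contractile lists had means of -0.04, -0.09 and -0.37 but stood above other genes in camera.

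**Figure D3:**
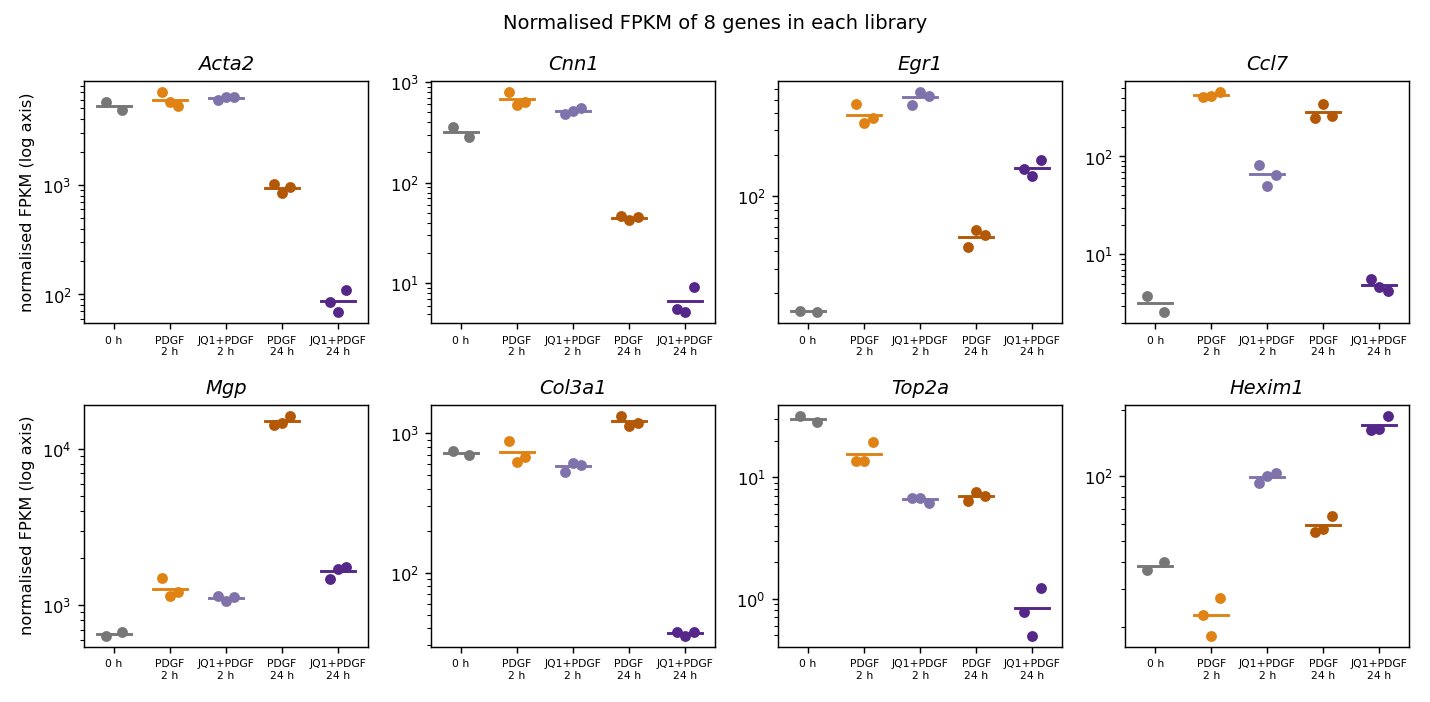
Normalised FPKM (log axis) of 8 genes in each library (points) with the group mean (line), by group. Acta2 falls from a mean of 945 with PDGF at 24 h to 87.9 with JQ1 plus PDGF, Col3a1 from 1221 to 36.7, and Hexim1 rises with JQ1 at both times.

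At 24 h, cells given JQ1 and PDGF had lower levels of contractile, matrix and mitosis genes than cells given PDGF alone, and higher levels of many immediate early genes. Of 23 contractile genes, 19 fell (19 adjusted over the list alone), and 18 fell and 1 rose on the median-centred scale. Acta2 went from 945 ± 87 to 87.9 ± 20.5 normalised FPKM (SD, n = 3 each), a difference of -3.43 ± 0.16 (limma, adjusted p = 1.73e-10). The integrin gene Itga8 fell by 3.20, Lmod1 by 3.01, Cnn1 by 2.62 and Tagln by 1.52, while Itga7, which PDGF had raised, fell by 2.67. Of 20 matrix genes, 18 fell and 1 rose (19 and 1 adjusted over the list alone, 17 and 2 centred). Eln, the elastin gene, went from 2399 ± 29.2 to 70.1 ± 18.3 (SD, n = 3 each), a difference of -5.11 ± 0.18 (adjusted p = 6.98e-12). Col3a1, a fibrillar collagen gene, fell by 5.01, the collagen and elastin crosslinking enzyme gene Lox stood at -4.87 ± 0.16 and Postn, the periostin gene, at -4.01 ± 0.12. Of 13 proteases and inhibitors, 9 fell and 2 rose (9 and 2 adjusted over the list alone, 5 and 3 centred), with the gelatinase gene Mmp2 at -4.20 ± 0.13 and Mmp14, its activator, at -2.18 ± 0.12. All 6 fibroblast markers fell (6 adjusted over the list alone, 4 centred), with Lum, the lumican gene, at -4.50 ± 0.12 and Pdgfra at -3.43 ± 0.20. The other markers moved as well: 4 of 5 endothelial markers fell (4 adjusted over the list alone), with Eng at -2.56 ± 0.15, and of the leukocyte markers Cd14 fell by 3.49 and Cd68 rose by 2.33 ± 0.40.

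All 22 G2/M genes fell with JQ1 at 24 h after PDGF (22 adjusted over the list alone, 21 centred). Ube2c stood at -2.99 ± 0.30 and Plk1 at -2.55 ± 0.19. Of 25 G1/S genes, 18 fell and 1 rose (18 and 1 adjusted over the list alone, 10 and 3 centred), with Rrm2 at -3.27 ± 0.24. Ccnd1 fell by 1.78 and Pdgfrb by 1.97. In the immediate early list 18 of 26 rose and 2 fell (18 and 2 adjusted over the list alone, 22 higher when centred). Atf3, a stress-induced transcription factor gene, rose by 3.41 ± 0.15, Nr4a1 by 1.81 ± 0.18 and Egr1 by 1.64 ± 0.14. Of 20 amino acid and ER stress genes, 7 rose and 4 fell (7 and 4 adjusted over the list alone, 15 and 2 centred). Ddit3, which encodes the stress factor CHOP, rose from 88.3 ± 3.43 to 598 ± 63.6 (SD, n = 3 each), and Chac1 rose by 2.01 ± 0.14, whereas Xbp1, a factor of the unfolded protein response, fell by 1.45. Of 21 ribosome biogenesis genes, 5 rose (5 adjusted over the list alone), and all 21 rose when centred, with Nop56 at 0.91 ± 0.13. Hexim1 rose by 1.52 ± 0.13 and Brd2 by 2.00 ± 0.24, and 2 of 7 BET and P-TEFb genes rose and 1 fell (2 and 1 adjusted over the list alone, 5 higher when centred). The median of that list was -0.09 and its mean 0.31.

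Of 16 inflammatory genes, 8 fell and 3 rose with JQ1 at 24 h after PDGF (9 and 3 adjusted over the list alone). Ccl7 stood at 283 ± 51.7 with PDGF and 4.82 ± 0.69 with JQ1 plus PDGF (SD, n = 3 each), a difference of -5.60 ± 0.18. The difference of Cxcl12 was -3.71 ± 0.15. Of 20 cholesterol genes, 17 fell and 1 rose (17 and 1 adjusted over the list alone, 12 and 3 centred), with Cyp51 at -1.49 ± 0.10. Of 17 glycolysis genes, 10 fell (10 adjusted over the list alone, 5 lower and 4 higher centred), with Pfkm at -1.90 ± 0.14. Of 30 state transcription factors, 17 fell and 3 rose (18 and 3 adjusted over the list alone, 12 and 7 centred). Prrx1 fell by 2.58 and Myocd by 1.17, whereas Klf4 rose by 1.39 ± 0.15. Spp1 fell by 0.87. Outside the lists and leaving microRNA loci aside, the genes that fell most included the Wnt pathway genes Wisp2 (-5.42 ± 0.17) and Sfrp2 (-5.40 ± 0.30). Plk5 (5.22 ± 0.32), the arrestin-domain gene Arrdc2 (4.07 ± 0.22), Serpinb2 (3.69 ± 0.23) and Pip5k1c (3.37 ± 0.15) were among the genes that rose most. The locus Mir214 was listed at 0 in all JQ1 plus PDGF libraries and at 260, 234 and 408 unnormalised FPKM with PDGF at 24 h. Values of such short loci, and of Rn28s, a ribosomal RNA gene in a polyadenylated library (-5.05 ± 1.22), are uncertain.

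In limma 5385 genes passed for JQ1 at 24 h, 467 higher and 4918 lower (2296 and 2588 on the median-centred scale), and 21 of the genes called on both scales had opposite directions. In camera the G2/M list (mean 1.44 below all other genes, adjusted p = 5.26e-09) passed, also with an estimated correlation (adjusted p = 0.0317). The immediate early (1.38 above, adjusted p = 3.05e-21), ribosome (0.89 above, 7.39e-11), matrix (1.58 below, 1.02e-08), contractile (0.99 below, 1.47e-05), amino acid (0.81 above, 1.69e-05), fibroblast (1.81 below, 0.00151), cholesterol (0.27 below, 0.00459) and BET (0.89 above, 0.0154) lists passed with the preset correlation. Their adjusted p was 0.0756, 0.19, 0.327, 0.327, 0.34, 0.19, 0.559 and 0.251 with an estimated correlation. G1/S (adjusted p = 0.175), inflammatory (0.567), protease (0.556), glycolysis (0.356), transcription factor (0.753) and endothelial (0.21) lists did not pass.

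The effect of JQ1 differed between 2 and 24 h for 2259 genes in limma's test of the interaction, with 488 more positive and 1771 more negative at 24 h (1332 and 1644 on the median-centred scale). Matrix genes were more negative at 24 h for 15 of 20 (16 adjusted over the list alone), G2/M genes for 13 of 22 (18) and contractile genes for 13 of 23 (17, with 1 more positive). Col3a1 differed by -4.69 ± 0.18 (adjusted p = 3.73e-10), with a JQ1 effect of -0.32 ± 0.12 at 2 h (adjusted p = 0.0524) and -5.01 ± 0.12 at 24 h. Ribosome biogenesis genes were more positive for 15 of 21 (18 adjusted over the list alone), immediate early genes for 14 of 26 with 1 more negative (16 and 1), and amino acid and ER stress genes for 12 of 20 with 3 more negative (12 and 3). Plk5 differed by 5.25 ± 0.45, Atf3 by 3.15 ± 0.22 and Trib3 by 3.10 ± 0.33, where Trib3 fell by 2.23 at 2 h and rose by 0.87 ± 0.23 at 24 h. The remaining counts, adjusted over all genes, were 6 more positive and 5 more negative of 16 inflammatory genes, 2 and 5 of 13 proteases, 2 and 7 of 17 glycolysis genes, 1 and 4 of 25 G1/S genes, 1 and 6 of 30 transcription factors and 1 and 2 of 7 BET genes. Adjusted over the list alone these were 8 and 5, 3 and 5, 2 and 7, 1 and 4, 1 and 6, and 1 and 2. Centred, the transcription factors split 6 and 6, the BET genes 2 and 1 and the cholesterol genes 1 and 4. Cholesterol genes were more negative for 6 of 20, fibroblast markers for 4 of 6 and endothelial markers for 2 of 5 (6, 6 and 2 adjusted over the list alone), and 1 of 2 leukocyte markers moved each way. JQ1 calls at both times shared a direction for 2720 genes and were opposite for 164. All 164 passed the interaction test, which their selection nearly fixes in advance, so this adds no support.

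Genes that PDGF raised were compared with those JQ1 lowered. At 2 h, 922 of the 1796 genes raised by PDGF (51.3%) were lower with JQ1, against 34% of all genes and 611 genes if the lists were independent. Of the 1282 genes lowered by PDGF, 173 were higher with JQ1 (93 if independent). Calls in the same direction were 150 higher in both (130 if independent) and 318 lower in both (436 if independent). At 24 h the counts were 2288 raised and then lower with JQ1 (1855 if independent), 34 lowered and then higher (23), 177 higher in both (176) and 310 lower in both (238). On the median-centred scale 721 genes were raised by PDGF and lower with JQ1 at 2 h (437 if independent) and 689 at 24 h (385). Genes lowered by PDGF and higher with JQ1 numbered 502 at 2 h (389 if independent) and 344 at 24 h (308). Calls in the same direction on that scale were 441 higher in both (408 if independent) and 324 lower in both (416) at 2 h, and 369 (341) and 466 (347) at 24 h. At 24 h on that scale, genes lower in both thus exceeded independence by more than genes lowered by PDGF and higher with JQ1. The PDGF libraries enter both comparisons. Across genes, which are not independent replicates, the PDGF and JQ1 differences had a covariance of -0.113 at 2 h and -0.083 at 24 h (-0.036 at each time in 100 draws simulated without any effect), and a Pearson correlation of -0.22 and -0.15 (simulated -0.45). The draws varied each gene independently, so shifts that a library shares across genes, such as those of the normalisation curve, are not in the simulated values. The 3 PDGF libraries of a time cannot be split into parts of 2, so part of the excess may come from the shared libraries.

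Leaving out unstimulated replicate 0 gave 546 in place of 922, 100 in place of 173, 125 in place of 318, 1336 in place of 2288, 21 in place of 34 and 114 in place of 177 genes. Leaving out unstimulated replicate 1 gave 105 in place of 173, 119 in place of 318 and 22 in place of 34, and leaving out PDGF 24 h replicate 0 gave 21 in place of 34.

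**Figure D4:**
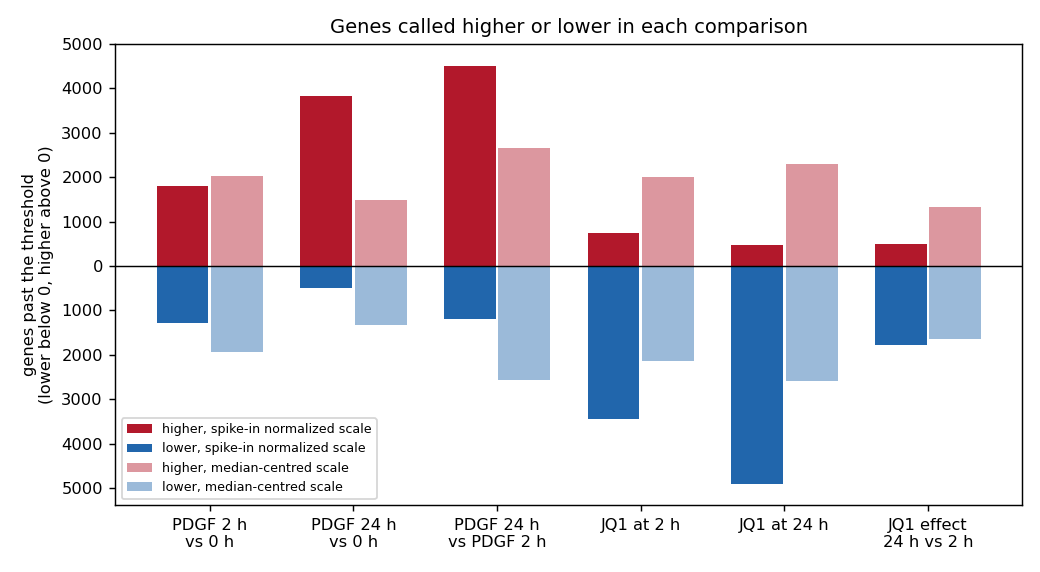
Number of genes past the limma threshold in each of 6 comparisons, higher above 0 and lower below 0, on the spike-in scale (dark bars) and the median-centred scale (light bars). With JQ1 at 24 h, 4918 genes are lower and 467 higher on the spike-in scale, against 2588 and 2296 on the median-centred scale.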

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

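The tests of the normalisation curve, the spike-in amounts, the global shift, the share of smooth muscle cells and the microRNA loci were chosen only after the result was seen; the splits of the samples and the arrangements of residuals were planned before their results.

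The effect of JQ1 differed between 2 and 24 h for 2259 genes in limma's test of the interaction, and this difference between the times is what singled out the genes named here. The interaction was 5.25 for Plk5, where JQ1 gave -0.03 at 2 h and 5.22 at 24 h, and 3.15 for Atf3 (0.26 and 3.41). It was 3.10 for Trib3 (-2.23 and 0.87), 3.21 for Cxcl1 (-2.27 and 0.94, the latter with adjusted p = 0.141), 3.19 for Mrps10 (-1.04 and 2.15) and -4.69 for Col3a1 (-0.32 and -5.01). The fitted values were -8.19 for Mir199a2, -4.64 for Mir214, -6.38 for Rn28s and -6.13 for Rpl37a. For the microRNA loci Mir199a2 and Mir214 these are no folds, since the loci were listed at 0 in whole groups. The calls of Mrps10, Mir199a2, Rn28s, Rpl37a and Mir214 were lost with robust variance (adjusted p = 0.0755, 0.072, 0.0702, 0.0784 and 0.114). Rpl37a also lost its call with no filter (adjusted p = 0.0503) and without PDGF 24 h replicate 0 (-5.46), JQ1 plus PDGF 24 h replicate 2 (-5.42) or replicate 0 (-5.30). Mir214 lost it on the unnormalised table (adjusted p = 0.0752), with size factors (0.0751), a pseudocount of 0.1 (0.0711) or no filter (0.0798), and without any single library of JQ1 plus PDGF at 2 h, PDGF at 24 h or JQ1 plus PDGF at 24 h, with values from -4.80 to -4.37.

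Other splits of the libraries were counted beside these results. For the interaction, 6 of 100 drawn splits, the real one included, called as many genes as the real one (2259). Exchanging libraries within a time carries the JQ1 effect shared by both times into the interaction, so these splits do not measure chance and nothing is concluded from them. The highest other split called 6193 genes by exchanging the labels of a whole time, which adds the JQ1 effects of both times. Only 1 of the 6 was such an exchange, and the highest split without it called 3483 genes, also more than the real one. When the residuals of a model without the interaction were arranged at random, 1 of 100 arrangements, the real one, called as many genes. The highest other called 1 gene. Those residuals still hold any interaction, which the arrangement turns into spread within groups, so few calls were likely. Chance is therefore not called excluded, and the count covers only the spread between these libraries. For 3 libraries against 3, 10 splits are too few for a share under 0.05. In each case 1 of 10 splits, the real one, called as many genes: 5703 for PDGF at 24 h against 2 h (highest other 0), 4183 for JQ1 at 2 h (highest other 4) and 5385 for JQ1 at 24 h (highest other 0).

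Most genes called with JQ1 at 24 h were lower on the spike-in scale. A normalisation curve distorting low values alone is argued against by the genes with a mean of at least 50 normalised FPKM, whose median log2 difference was -0.42. The same curve also moved high values, by 0.37, 0.44 and 0.42 (log2) in the PDGF 24 h libraries. With JQ1 plus PDGF at 24 h it moved them by -0.14, -0.23 and 0.09. The value of -0.42 thus does not speak against the normalisation making the shift, and the median on the unnormalised table was -0.004. Unequal spike-in amounts between the groups cannot be told apart from less RNA per cell, because the mean spike-in share was 1.36 times as high with JQ1 and the groups did not overlap. A lower RNA content per cell with JQ1 stays open as a biological explanation and was not tested.

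Contractile and matrix genes fell with JQ1 at 24 h. A global shift of the spike-in scale is argued against by the median-centred scale, where the contractile list stood at -1.07 against all other genes. A lower share of smooth muscle cells would raise the markers of whichever other cell type took their place. On that scale the medians were -1.95 for 6 adventitial fibroblast, -1.28 for 5 endothelial and -0.15 for 2 leukocyte markers. Of the latter, Cd68 rose by 2.33 and Cd14 fell by 3.49 on the spike-in scale. Only 5 of 12 endothelial and 2 of 12 leukocyte markers reached 1 normalised FPKM in at least 2 libraries. For the listed markers, this argues against a large share of these cells in any group. The few tested markers cannot decide the rest of the question. Smooth muscle cells may express some of them, and Eng, Pdgfra and Cd14 also moved with PDGF. A smaller change in the share of cell types, or one that involves other cells, is therefore left open. A candidate explanation that stays open is that BET inhibition lowers these genes in the cells themselves; this is a hypothesis, since it was found in the same data and no test here decides it. Libraries with JQ1 alone and counts of the cell types in the same cultures would test it.

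MicroRNA loci were among the largest folds. The median residual SD of these loci was 13.2 times that of other tested genes, as few reads on short loci would give. This may account for the size of their folds, and no biological explanation was tested.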

How the results depend on the processing

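The alternative without PDGF 2 h replicate 1 and PDGF 24 h replicate 0, and the list counts on other scales, were chosen after seeing the data; the other tests were planned. The 6 counts of genes stayed within 1.5 times their value with spike-in medians, a pseudocount of 0.1, no filter, a filter of 5 FPKM, robust variance and without those 2 libraries. With a log2 difference of at least 1 as well, 1236 (PDGF 2 h), 1454 (PDGF 24 h), 2315 (24 against 2 h), 1309 (JQ1 2 h), 2467 (JQ1 24 h) and 1310 (interaction) genes passed, since that threshold leaves fewer genes. PDGF at 2 h gave 1537 genes with only the compared groups in the fit, and PDGF at 24 h gave 2826 on the unnormalised table and 2821 with size factors. The size factors were nearly equal in all libraries, so the unnormalised table and size factors are nearly the same check. Leaving out each library gave 1601 to 3154 genes (PDGF 2 h), 2489 to 3909 (PDGF 24 h), 4975 to 5783 (24 against 2 h), 3437 to 4492 (JQ1 2 h), 4423 to 5537 (JQ1 24 h) and 1720 to 2566 (interaction). A lone unstimulated library was assumed to vary like the other groups. On the unnormalised table and with size factors, the overlaps were 501 and 502 (lower with PDGF and higher with JQ1 at 2 h), 432 and 441 (higher in both at 2 h), 688 and 689 (higher with PDGF and lower with JQ1 at 24 h), 345 and 344 (lower and then higher at 24 h), 366 and 369 (higher in both at 24 h) and 470 and 466 (lower in both at 24 h). Leaving out each library gave, at 2 h, 546 to 1182 (higher then lower), 100 to 185 (lower then higher), 105 to 135 (higher in both) and 119 to 349 (lower in both), and at 24 h 1336 to 2503, 21 to 31, 114 to 170 and 223 to 324 in that order. Without PDGF 2 h replicate 1 and PDGF 24 h replicate 0, counts of list members that moved by over 1.5 times and by more than 1 gene were 5 higher and 2 lower contractile genes with PDGF at 2 h, 1 and 6 with JQ1 at 2 h, 2 higher ribosome genes with PDGF at 24 h, 8 higher ribosome genes with JQ1 at 24 h and 3 inflammatory genes more positive in the interaction. Of 75 list tests, 30 lost the threshold with a correlation estimated on the spike-in scale, and 27 gained it with fry. For these lists no correlation was estimated on the median-centred scale. Fry passed in the direction opposite to camera for the fibroblast list with PDGF at 24 h (0.318), the matrix list between 2 and 24 h (0.172) and the contractile list with JQ1 at 2 h (-0.37). It was also opposite, without passing, for the ribosome list with PDGF at 24 h (0.25), the cholesterol list between 2 and 24 h (0.22) and the immediate early (-0.04) and glycolysis (-0.09) lists with JQ1 at 2 h. Of the 193 gene results named in the text, 190 kept direction and side of the threshold on the unnormalised table. The text drew its examples by preference from genes whose calls held, after their values were seen, and over all 435 results that the naming rule gave, 403 kept them and 3 reversed. Beyond what a stricter threshold explains, the cause was not tested. No paired analysis was possible because the columns carry neither replicate letters nor bar codes. The block by replicate letter and the block by bar-code set were not run. In the sample titles, libraries without JQ1 carry letters from A to D and those with JQ1 letters from E to H. A block by letter could therefore not have paired JQ1 with PDGF libraries. Whatever the letters stand for cannot be told apart from JQ1. With depth unknown, changes of low values are the least certain.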

Other observations

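The test reported in this part was planned before its result was seen; the genes named here were chosen after their values were seen.

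Because Igtp, Oas1b and Oasl2 were among the genes that fell most with JQ1 at 2 h, a hypothesis was that interferon-response genes as a set are lower with JQ1. A list of 36 other interferon-response genes, 0 of them in another list, had 29 tested members. With JQ1 at 2 h, 27 fell and 0 rose in limma (23 fell on the median-centred scale). The list mean on the median-centred scale was -1.02 against all other genes (camera p = 3.13e-10, and 0.00012 with an estimated correlation), and on the spike-in scale it was -0.99 (camera p = 2.7e-08, and 0.053 with an estimated correlation). Irgm stood at -2.87, Isg15 at -2.12 and Ddx58 at -1.99. At 24 h, 23 fell and 1 rose (19 and 1 median-centred), with Ifitm3 at -3.66 and Gbp2 at -3.02. Rsad2 was the exception at 1.04 (-1.03 at 2 h). The list mean against all other genes at 24 h was -0.83 median-centred (camera p = 2.63e-06, and 0.000968 with an estimated correlation). On the spike-in scale it was -0.77 (camera p = 0.000212, and 0.172 with an estimated correlation). With PDGF alone at 2 h, 23 of these genes rose and 1 fell. The hypothesis came from genes of the same libraries, so the fall of this list is not independent support for it. That JQ1 lowers a broad set of interferon-response genes in these cells remains a hypothesis. Libraries with JQ1 alone would be needed to separate such a lowering from the PDGF response.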
